A study of Mus musculus with 6 samples.

How the data were processed

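The data were counts of single guide RNAs (sgRNAs) from a CRISPR interference screen in mouse neuronal progenitor cells. The cells expressed dCas9-KRAB, a nuclease-dead Cas9 fused to a repressor domain that lowers transcription at the promoter an sgRNA points to, and carried floxed alleles of Upf2, a core factor of nonsense-mediated mRNA decay. A lentiviral library of 3630 sgRNAs against epigenetic regulators was introduced, and the cells then received a Cre construct, which deletes Upf2, or a GFP construct as the control, per the labels' protocols. Of the 6 libraries, 2 carry Cre in their titles, 2 carry GFP and 2 carry only the word sgRNA. The treatment of the last pair is not given in the sources used here. Each pair holds a title with the number 05 and one with 50, whose meaning is also not given.

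The deposited file holds raw read counts per sgRNA, with no normalization. Integrated sgRNA sequences were amplified by PCR and read from a single end on a NextSeq550 instrument, per the labels' protocols. Per the submitters' processing notes, bcl2fastq 2.20.0.422 and MAGeCK 0.5.9.3 were used. The mismatch rule, read trimming and filters of the counting are not given in the sources used here. The counts measure the abundance of cells that carry each sgRNA and not the expression of any gene, so they do not check the Upf2 deletion, and no marker of another cell type can be read from them. Loss of an sgRNA can follow from growth, survival or sampling of cells, and PCR and a small number of founder cells can move single sgRNAs. Reads carried no molecular identifiers, so reads of one sgRNA are not independent molecules. The library held 720 genes with 5 sgRNAs each and 30 sgRNAs under the label msCon, which matched no mouse gene. The names fixed for control sgRNAs before the data were examined matched 0 labels. The msCon sgRNAs were therefore taken as the reference set after the file had been seen, and the file does not say what they target. Of the gene names, 693 matched a current symbol in the mouse RefSeq table of GRCm38.p6, 26 matched by a synonym and 1 had no match. The sources used here name no genome build, so no sgRNA coordinates are given.

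Library totals ran from 2394549 to 3571967 counts, with medians of 379 to 587 counts per sgRNA. The filter filterByExpr of edgeR (minimum count 10, minimum total 15) kept 3595 sgRNAs and removed 35; 28 msCon sgRNAs were kept. Counts were tested with edgeR 4.0.16 in R 4.3.3. The test used trimmed-mean (TMM) factors, a quasi-likelihood fit with robust dispersion over all 6 libraries, a term for the 3 groups and no term for the title number. A shared fit was used because each group has 2 libraries. The common dispersion was 0.157, a biological coefficient of variation of 0.396. Values within a title number are differences of log2 CPM with a prior count of 2.

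A gene's value is the mean log2 fold change of its kept sgRNAs, with the standard error (SE) over those sgRNAs. It was tested with camera of limma 3.58.1 on the same data, with a preset correlation of 0.01 between the sgRNAs of a set, for genes with at least 3 kept sgRNAs, which held for all 720. Camera asks whether a gene's sgRNAs moved relative to all other sgRNAs. Gene lists were tested in the same way over all sgRNAs of their members. With the preset correlation, the sgRNAs of one gene then count as nearly independent members of its list. The alternative of random gene lists takes genes as the unit, so a list can pass by camera and not against random lists. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method at 0.05 over the sgRNAs, the genes or the lists of one comparison. A list's SE is over its genes. The count "adjusted over the list alone" adjusts the gene p-values within a list.

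The comparisons, tests, lists and alternatives were fixed before the data were examined. The 21 lists were PRC2, PRC1, SWI/SNF (BAF), NuRD, COMPASS/MLL, TIP60/NuA4, INO80/SRCAP, SAGA/ATAC, MOZ/HBO1/MSL acetyltransferases, histone deacetylases and sirtuins, BET and elongation factors, DNA methylation and its readers, H3K9 methylation and HP1, histone demethylases, arginine methyltransferases, cohesin and CTCF, histone chaperones and chromatin assembly, mitotic kinases and the chromosomal passenger complex, the p53 pathway and DNA damage response, nonsense-mediated decay, and genes broadly essential in cultured cells. The library held 0 of the 15 nonsense-mediated decay genes, Upf2 among them, which left 20 lists with at least 3 genes. Lists share members: Aurkb and Birc5 are in both the mitotic and the essential list, and Smc1a, Smc3 and Rad21 in both the cohesin and the essential list. Of the 13 genes of the cohesin and CTCF list the library held only these 3, and not Ctcf.

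Genes were named by a fixed rule. For Cre against GFP, these are up to 10 genes per direction with the largest mean change among those past the threshold and of one sign in both title numbers, and for the other comparisons up to 5. Where fewer than 5 passed in a direction, those of smallest p filled the places up to 5 and are said not to pass. Trp53, 2 to 4 members of each list past its threshold and up to 3 sgRNAs per direction are also named. Where an sgRNA had 0 counts in every library of a group, a value with that group set at 3 counts is given too.

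Alternatives tried were the title number as a block, DESeq2 size factors, total counts alone, no low count filter beyond 1 count in all, a mean of at least 100 counts, only the 2 groups compared, each library left out in turn, the Wald test of DESeq2 1.42.0, camera with an estimated correlation, counts summed per gene, fry, robust rank aggregation of sgRNA p-values (own code, alpha 0.25, 10000 random sets), 10000 random gene lists, a prior count of 10 and libraries thinned to the smallest total. Factors from the msCon sgRNAs, a fit without the Trp53 sgRNAs and lists with each library left out were added after the data had been seen.

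The tests were run on simulated data for Cre against GFP, with 40 of 720 genes changed. Each sgRNA was drawn independently, with a dispersion that was the same in all libraries, and all sgRNAs of a changed gene shifted alike. In the data the sgRNAs of a gene could differ, as for Snrpa in Cre over GFP, from 0.48 to 2.97. The simulation therefore does not show how many false calls arise where sgRNAs of a gene move together or groups differ in spread. Of 99 sgRNAs changed by a log2 of 1, edgeR recovered 10, and of 100 changed by a log2 of 2 it recovered 74. It made 3 false calls among the unchanged sgRNAs. Camera recovered 11 of 20 genes changed by a log2 of 1 and 20 of 20 changed by a log2 of 2, with 0 false calls among the unchanged genes. Camera with an estimated correlation and fry each recovered 0 genes of either size in the same simulation. Robust rank aggregation recovered 11 and 20, and counts summed per gene 16 and 20 with 2 false calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.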

Results

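Integrated sgRNAs were counted in 6 libraries of mouse neuronal progenitor cells expressing dCas9-KRAB: 2 from cells given Cre to delete Upf2, 2 from cells given GFP, and 2 named only sgRNA. The comparison of Cre with GFP asks which repressed genes altered the abundance of cells after loss of Upf2. The comparisons with the sgRNA libraries have no stated purpose, and because the treatment of those libraries is not given, they describe differences between libraries and not a time course. Total counts were 3571967, 2657566 and 2626417 in the Cre, GFP and sgRNA libraries numbered 05, and 2554566, 2445005 and 2394549 in those numbered 50. No source says that the numbers mark separate cultures or animals. They may be technical repeats or 2 conditions, so p-values of single sgRNAs measure only the spread between these libraries. Camera compares the sgRNAs of a gene or list with all other sgRNAs, so its p-values measure a spread over sgRNAs. A very small p by camera therefore does not show how well a result repeats between libraries.

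sgRNAs against Trp53, which encodes the tumour suppressor p53, took a very different share of the counts in each kind of library. The 5 Trp53 sgRNAs held 21.1% of all counts in Cre 05 (exact 95% binomial interval 21.1 to 21.2) and 19.1% in Cre 50 (19.0 to 19.1). They held 5.80% in GFP 05 (5.78 to 5.83) and 4.39% in GFP 50 (4.36 to 4.41), and 0.411% in sgRNA 05 (0.404 to 0.419) and 0.260% in sgRNA 50 (0.254 to 0.267). These intervals cover counting error only. The mean share was 20.1% ± 1.44 (SD, n = 2) with Cre, 5.09% ± 1.0 (SD, n = 2) with GFP and 0.336% ± 0.107 (SD, n = 2) in the sgRNA libraries. The smallest p that an exact permutation test can give for 2 libraries against 2 is 0.333, so shares are given as values.

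Counts were also less even in the Cre and GFP libraries. The Gini index, which is 0 when every sgRNA has the same count, was 0.609 with Cre, 0.545 with GFP and 0.415 in the sgRNA libraries (means, n = 2 each). It includes the Trp53 sgRNAs, at 20.1% of counts with Cre and 5.09% with GFP, and was not computed without them. The higher index with Cre than with GFP is therefore not separate from the Trp53 share. sgRNAs at 0 counts numbered 75, 97 and 9 in Cre, GFP and sgRNA 05 and 43, 44 and 17 in Cre, GFP and sgRNA 50. The 2 libraries of a group had a chi-square per degree of freedom of 93.1 for Cre, 67.2 for GFP and 12.7 for sgRNA against read counting alone. PCR raises such values too, so they do not show whether the numbers mark separate cultures, and each library was kept by itself. The SD across sgRNAs of the log2 difference between 05 and 50 was 1.11 for Cre, 1.12 for GFP and 0.44 for sgRNA. The mean log2 fold change of the 28 kept msCon sgRNAs was 0.04 ± 0.10 (SE over sgRNAs) for Cre over GFP, 0.23 ± 0.14 for GFP over sgRNA and 0.26 ± 0.16 for Cre over sgRNA, and 0 of them passed the edgeR test in any of these. The SD of these fold changes across the 28 msCon sgRNAs was 0.54, 0.76 and 0.83. Between 05 and 50, the SD of their log2 difference was 1.58 for Cre, 0.75 for GFP and 0.34 for sgRNA. For Cre this was above the 1.11 of all sgRNAs.

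**Figure D1:**
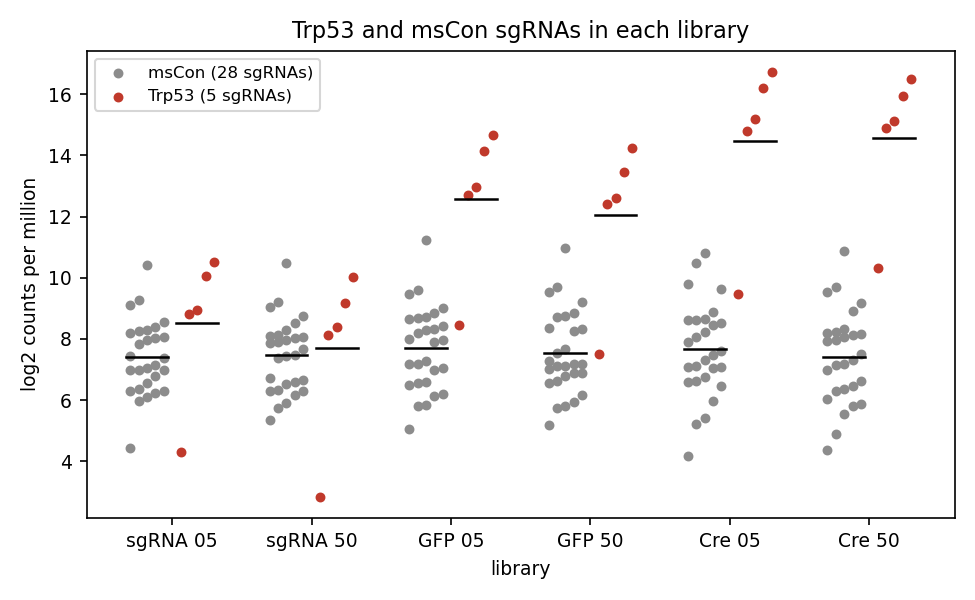
Log2 CPM (vertical axis) of the 5 Trp53 sgRNAs and of the 28 msCon sgRNAs in each of the 6 libraries, one point per sgRNA and a bar at the mean. The Trp53 means are 14.48 and 14.56 in the Cre libraries, 12.59 and 12.04 in the GFP libraries and 8.53 and 7.71 in the sgRNA libraries, while the msCon means lie between 7.40 and 7.70.

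Trp53 sgRNAs rose most in Cre over GFP, by a mean log2 fold change of 2.19 ± 0.08 (SE over 5 sgRNAs; 4.56-fold; adjusted p = 4.65e-23 by camera), with 1.89 in 05 and 2.52 in 50. Snrpa, a protein of the U1 particle, rose by 1.70 ± 0.51 (adjusted p = 0.00205), Snrnp48, of the minor spliceosome, by 1.38 ± 0.35 (adjusted p = 0.0203), and Gemin2, of the SMN assembly complex, by 1.36 ± 0.21 (adjusted p = 0.00106). Tada3 and Tada2a, adaptor subunits of histone acetyltransferase complexes, rose by 1.58 ± 0.37 (adjusted p = 0.00106) and 1.0 ± 0.44 (adjusted p = 0.0240). Prmt5, an arginine methyltransferase that modifies Sm proteins and histones, rose by 1.19 ± 0.30 (adjusted p = 0.0203), Wdr61, a subunit of the PAF1 and SKI complexes, by 1.10 ± 0.11 (adjusted p = 0.0267), and Atm, a kinase activated by DNA breaks, by 0.90 ± 0.10 (adjusted p = 0.0173). All 5 sgRNAs of each of these 9 genes were higher with Cre.

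Trp53bp1, which encodes a p53-binding protein of double-strand break repair, fell, with a mean of −1.14 ± 0.63 (adjusted p = 0.0488), −1.55 in 05 and −0.56 in 50. It did not pass with DESeq2 size factors (adjusted p = 0.0559), with msCon factors (adjusted p = 0.0606), or without the Trp53 sgRNAs (adjusted p = 0.0581). The genes of next smallest p among those lower with Cre did not pass. They were Daxx, a histone H3.3 chaperone, at −0.65 ± 0.19 (adjusted p = 0.0924; adjusted p = 0.0346 without Cre 50), Men1, which encodes menin, at −0.55 ± 0.21 (adjusted p = 0.0992), Mtr, methionine synthase, at −0.70 ± 0.26, and Psd3 at −0.87 ± 0.34 (both adjusted p = 0.139). Of the 10 genes past the threshold, 9 were higher and 1 lower, each with one sign in both title numbers.

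Several of the genes that were higher in Cre than in GFP were lower in GFP than in the sgRNA libraries, a comparison that shares the GFP libraries. Mean log2 GFP over sgRNA was −2.17 for Snrpa, −2.48 for Snrnp48, −1.87 for Gemin2, −1.95 for Prmt5, −1.81 for Wdr61 and −1.68 for Tada2a, all past the threshold, while Tada3 at −1.0 and Atm at 0.35 did not pass. Their means in Cre over sgRNA were −0.47, −1.10, −0.51, −0.76, −0.71 and −0.68 for the first 6, none past the threshold, 0.58 for Tada3, also not past it, and 1.25 for Atm, which passed.

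Single libraries decided most of these calls. Without Cre 05, 1 of the 10 genes passed, Trp53, and 5 passed without GFP 50, 4 of them among the 10. Trp53 passed in each of the 6 fits that left out a library, with means from 1.95 to 2.48. Gemin2, Tada3, Prmt5 and Wdr61 passed in 4 of the 6, Snrpa, Snrnp48 and Atm in 3, Trp53bp1 in 2 and Tada2a in 1. Means moved by over 1.5 times for Gemin2 and Wdr61, to 0.86 and 0.67 without Cre 05, and for Trp53bp1, to −0.74 without GFP 05. By counts summed per gene Trp53, Tada3 and Atm passed and the other 7 did not (adjusted p from 0.0704 to 0.328). The value of Trp53bp1 by summed counts was −0.33, nearer 0 than its mean over sgRNAs. By robust rank aggregation Trp53, Tada3, Atm and Gemin2 passed and the other 6 did not (adjusted p from 0.144 to 0.203), and fry called 0 genes (105 at an unadjusted p below 0.05). With only the Cre and GFP libraries in the fit, Snrnp48 (adjusted p = 0.052) and Tada2a (adjusted p = 0.113) did not pass. With an estimated correlation, camera called 0 genes (4 at an unadjusted p below 0.05), with an adjusted p of 0.998 for each of the 10.

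**Figure D2:**
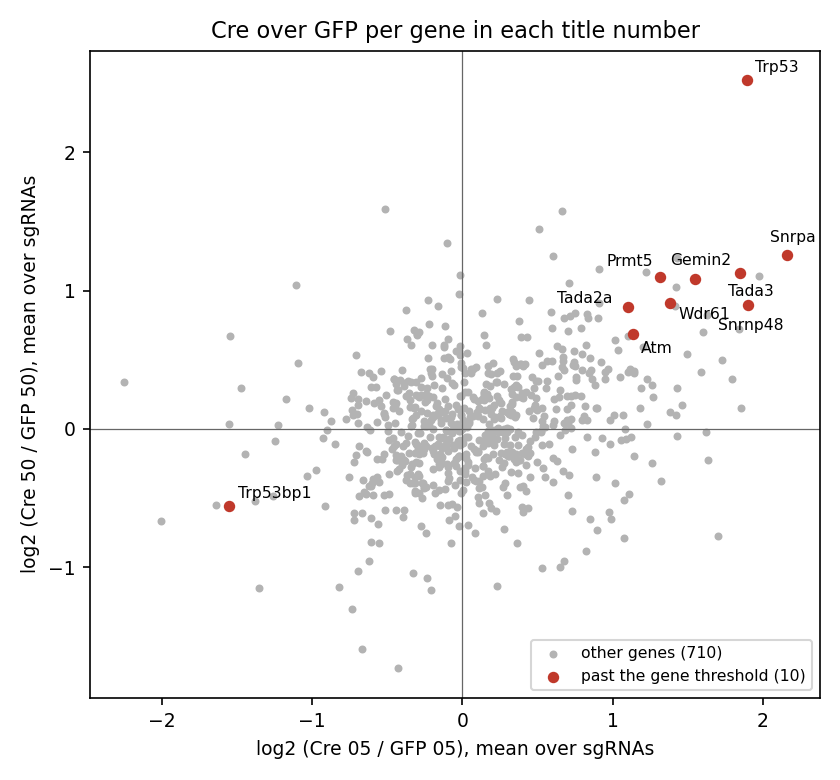
Mean log2 Cre over GFP of each of the 720 genes in the libraries numbered 05 (horizontal axis) and 50 (vertical axis), with the 10 genes past the camera threshold in red. Trp53 lies at 1.89 and 2.52 and Trp53bp1 at −1.55 and −0.56, and across genes the Pearson correlation between the axes is 0.314.

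Of single sgRNAs, edgeR called 4 as higher with Cre than with GFP and 0 as lower, with 366 at an unadjusted p below 0.05; the Wald test of DESeq2 called 54 higher and 12 lower. Of the 4, 3 target Trp53. They are sg_Trp53_i3 at 2.37 ± 0.27 and sg_Trp53_i1 at 2.28 ± 0.25 (SE of the fit; both adjusted p = 0.0127), and sg_Trp53_i5 at 2.15 ± 0.29 (adjusted p = 0.0311). The fourth, sg_Mgea5_i3, named after its value was seen, was at 2.08 ± 0.23 (adjusted p = 0.0127), while Mgea5, which encodes the enzyme that removes O-GlcNAc, had a mean of 0.40 ± 0.55 over 5 sgRNAs and did not pass. The count was 0 without GFP 05, without GFP 50 or with factors from the msCon sgRNAs (323, 630 and 361 at an unadjusted p below 0.05), 10 without Cre 05 and 23 without Cre 50. With total counts in place of TMM factors, 4 sgRNAs were called higher and 1 lower.

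Among the gene lists, the p53 pathway and DNA damage response was higher with Cre than with GFP, at a mean of 0.48 ± 0.28 over 11 genes (adjusted p = 0.00095; adjusted p = 0.363 with an estimated correlation; adjusted p = 0.054 against random lists). Within it Trp53 and Atm rose, Trp53bp1 fell and 8 genes did not pass; adjusted over the list alone, 3 were higher and 1 lower. Parp1, a sensor of DNA strand breaks, had a mean of 1.22 ± 0.43 over 4 sgRNAs and did not pass. Brca2, of homologous recombination, had one sgRNA at 0 in both GFP libraries. Its mean was 0.50 with GFP at 3 counts for that sgRNA, its median was 0.62, and the list mean was then 0.42. The members that passed act in opposite directions here, so the list's mean is not a common shift. With total counts the mean was 0.24 (adjusted p = 0.0017 by camera). Without the Trp53 sgRNAs 0 lists passed by camera (3 at an unadjusted p below 0.05), with a mean of 0.37 for the p53 list (adjusted p = 0.402) and also 0.37 for the broadly essential list (adjusted p = 0.0504).

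The broadly essential list was also higher with Cre than with GFP, at a mean of 0.31 ± 0.07 over 41 genes (adjusted p = 0.0257; adjusted p = 0.61 with an estimated correlation; adjusted p = 0.032 against random lists). Prmt5 rose and 40 genes did not pass, and adjusted over the list alone the count was also 1. Total counts, which moved the median of all sgRNAs to −0.24, put the list mean at 0.06. Its test, relative to all sgRNAs, then still pointed higher (adjusted p = 0.0066 by camera). Members of largest mean were Hdac3, the deacetylase of the NCoR complex, at 1.46 ± 0.61, Ruvbl1, an ATPase of several remodelling complexes, at 1.11 ± 0.40, and Wdr5, of the COMPASS complexes, at 0.94 ± 0.30, none past the gene threshold. Its mean was −0.00 without Cre 05 (adjusted p = 0.688), 0.20 without Cre 50 (adjusted p = 0.00578) and 0.57 without GFP 50, where both lists had an adjusted p of 0.232. The p53 list was at 0.32 without Cre 05 (adjusted p = 0.0654).

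The other 18 lists did not pass for Cre over GFP, with adjusted p from 0.0588 to 0.848. SAGA/ATAC came nearest, at 0.29 ± 0.11 over 19 genes (adjusted p = 0.0588), with Tada3 and Tada2a higher both over all genes and adjusted over the list alone. Means were 0.29 ± 0.14 for arginine methyltransferases, 0.27 ± 0.21 for INO80/SRCAP, 0.22 ± 0.10 for TIP60/NuA4, 0.19 ± 0.11 for COMPASS/MLL and 0.14 ± 0.09 for MOZ/HBO1/MSL. They were 0.07 ± 0.07 for the mitotic list, 0.06 ± 0.12 for PRC2, 0.03 ± 0.10 for histone demethylases, 0.02 ± 0.10 for DNA methylation and 0.02 ± 0.09 for BET and elongation, and in these the test pointed lower, relative to all sgRNAs. They were −0.02 ± 0.14 for histone chaperones, −0.04 ± 0.14 for histone deacetylases and sirtuins, −0.05 ± 0.09 for SWI/SNF, −0.06 ± 0.08 for NuRD, −0.10 ± 0.07 for PRC1 and −0.14 ± 0.16 for H3K9 methylation and HP1. Cohesin and CTCF had a mean of −0.08 ± 0.13 while its test pointed higher.

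In GFP over the sgRNA libraries, 45 genes passed, 9 higher and 36 lower. Trp53 rose by 4.17 ± 0.08 (18.0-fold; adjusted p = 1.01e-34), with 4.06 in 05 and 4.33 in 50. Trp53bp1 rose by 1.64 ± 0.36 (adjusted p = 0.000412), Kdm5c, an H3K4 demethylase, by 1.26 ± 0.16 (adjusted p = 0.0202), Men1 by 1.16 ± 0.43 (adjusted p = 0.00109) and Brms1l, of the SIN3 deacetylase complex, by 0.99 ± 0.09 (adjusted p = 0.0344). Among the losses, Hdac3 fell by 2.64 ± 0.69 (adjusted p = 0.00943), Snrnp48 fell by 2.48 ± 0.41 (adjusted p = 0.000319), Emg1, which modifies ribosomal RNA of the small subunit, fell by 2.39 ± 0.35 (adjusted p = 0.00504) and Ruvbl1 fell by 2.28 ± 0.29 (adjusted p = 0.00251; a mean of −3.46 without GFP 50). Brca2 also fell (adjusted p = 0.0357), with a mean of −2.29 when the sgRNA at 0 in GFP is set at 3 counts and a median of −1.77. With an estimated correlation 0 genes passed (18 at an unadjusted p below 0.05), with an adjusted p of 0.853 for each gene named here, and without GFP 50 the count was 24, of which 21 were among the 45. Of the genes named here, Kdm5c (adjusted p = 0.0699), Brms1l (adjusted p = 0.143) and Brca2 (adjusted p = 0.0951) did not pass without GFP 50, nor Brca2 without GFP 05 (adjusted p = 0.102), with total counts (adjusted p = 0.0563), with msCon factors (adjusted p = 0.0521) or with a mean of at least 100 counts (adjusted p = 0.101). By fry, Trp53bp1, Kdm5c, Brms1l, Snrnp48, Emg1 and Brca2 did not pass (adjusted p from 0.0538 to 0.192), nor Emg1 and Brca2 by robust rank aggregation (adjusted p = 0.0518 and 0.125).

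Single sgRNAs in GFP over sgRNA numbered 23 higher and 35 lower by edgeR. The largest gains past the threshold were all of Trp53, with sg_Trp53_i2 at 4.38 ± 0.59, sg_Trp53_i3 at 4.28 ± 0.30 and sg_Trp53_i5 at 4.18 ± 0.31 (adjusted p = 0.00964, 0.000174 and 0.000249). Among sgRNAs past the threshold the largest losses were sg_Tada2a_i2 at −3.70 ± 0.46 (adjusted p = 0.00697), sg_Snrnp48_i1 at −3.33 ± 0.59 and sg_Parp1_i2 at −3.16 ± 0.56 (both adjusted p = 0.0330). sg_Tada2a_i2 had 48 and 49 counts in the GFP libraries and 726 and 719 in the sgRNA libraries. The total of 58 moved to 6, 8, 12 and 9 without GFP 05, GFP 50, sgRNA 05 and sgRNA 50, and to 213 and 229 without Cre 05 and Cre 50, which enter only the estimate of spread. Scaling by total counts moved the median of all sgRNAs from 0.06 to −0.16 and the split to 23 higher and 162 lower, and msCon factors moved it to −0.20 with 14 higher and 174 lower, so directions here are relative to the TMM centre.

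The broadly essential list fell in GFP over sgRNA, with a mean of −1.19 ± 0.10 over 41 genes (adjusted p = 4.26e-18; adjusted p = 0.224 with an estimated correlation; adjusted p = 0.002 against random lists). Of its members 12 fell, 0 rose and adjusted over the list alone 20 fell. Hdac3 and Ruvbl1 were among the 12, as was Ruvbl2, the partner ATPase of Ruvbl1, at −2.09 ± 0.13 (adjusted p = 0.0229; adjusted p = 0.0541 without GFP 50, 0.0606 with a mean of at least 100 counts, 0.0677 by fry and 0.0518 by robust rank aggregation), while Hcfc1, a host cell factor of the COMPASS complexes, at −2.06 ± 0.84 did not pass. The mitotic list of 4 genes fell too, at −1.02 ± 0.51 (adjusted p = 0.0286; adjusted p = 0.269 with an estimated correlation; adjusted p = 0.256 against random lists). In it Aurkb, the kinase of the chromosomal passenger complex, fell by 1.72 ± 0.28 (adjusted p = 0.0296; adjusted p = 0.138 without GFP 50 and 0.262 by robust rank aggregation), and adjusted over the list alone 2 fell. Aurka was at −1.46 ± 0.41, Birc5, which encodes survivin, at −1.40 ± 0.47 and Gsg2, haspin, at 0.49 ± 0.30. The mitotic list was lost without GFP 50 (adjusted p = 0.16).

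The other 18 lists did not pass for GFP over sgRNA, with adjusted p from 0.0523 to 0.800. Means were −0.88 ± 0.27 for cohesin and CTCF, −0.51 ± 0.23 for TIP60/NuA4, −0.48 ± 0.25 for arginine methyltransferases, −0.48 ± 0.24 for histone chaperones, −0.44 ± 0.22 for COMPASS/MLL, −0.39 ± 0.36 for INO80/SRCAP, −0.37 ± 0.21 for BET and elongation, −0.27 ± 0.16 for SAGA/ATAC and −0.17 ± 0.12 for DNA methylation. MOZ/HBO1/MSL had a mean of −0.28 ± 0.16 and a median of 0.04. PRC1 was at 0.14 ± 0.08, H3K9 methylation and HP1 at 0.06 ± 0.16 and histone demethylases at 0.05 ± 0.13. The p53 list, at a mean of −0.15 ± 0.59 and a median of −0.06, histone deacetylases and sirtuins, at −0.05 and 0.10, PRC2, at −0.07 and 0.02, NuRD, at −0.10 and −0.10, and SWI/SNF, at −0.00 and 0.10, had tests that pointed higher relative to all sgRNAs.

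In Cre over the sgRNA libraries, Trp53 rose by 6.36 ± 0.08 (82.4-fold; adjusted p = 4.44e-88), with 5.95 in 05 and 6.85 in 50. Atm rose by 1.25 ± 0.31 (adjusted p = 0.000117), Crebbp, a histone acetyltransferase, by 0.94 ± 0.34 (adjusted p = 0.0385), Bcor, a corepressor of a variant PRC1 complex, by 0.86 ± 0.44 and Tada1, a SAGA subunit, by 0.83 ± 0.36 (both adjusted p = 0.0365). Snrnp200, a helicase of the spliceosome, fell by 1.79 ± 0.26, Bub3, of the spindle checkpoint, fell by 1.57 ± 0.13, Birc5 fell by 1.52 ± 0.29 and Ash2l, of the COMPASS complexes, fell by 1.18 ± 0.12 (adjusted p = 0.0365, 0.0365, 0.0365 and 0.0365). Aurkb fell by 1.51 ± 0.23 (adjusted p = 0.0385). Outside the naming rule, Actb, which encodes beta-actin, rose by 0.82 ± 0.12 and Snrnp40, a spliceosome protein, fell by 1.08 ± 0.21, named after their values were seen, to a total of 6 genes higher and 6 lower.

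Of the genes named for Cre over sgRNA, Trp53 and Atm passed in all 6 fits that left out a library, Bub3, Tada1 and Ash2l in 4, Snrnp200, Crebbp and Aurkb in 3, and Birc5 and Bcor in 2. Without Cre 50 the mean of Aurkb was −3.15 and that of Tada1 0.48. The count of genes was 11 without Cre 05, 3 without Cre 50, 12 without sgRNA 05, 8 without sgRNA 50, 24 without GFP 05 and 20 without GFP 50, of which 5, 2, 7, 7, 12 and 11 were among the 12. With an estimated correlation 0 genes passed (10 at an unadjusted p below 0.05), with an adjusted p of 0.970 for each gene named as past. With total counts, which moved the median of all sgRNAs to −0.47, 5 genes passed. Crebbp, Bcor and Tada1 were then at 0.47, 0.39 and 0.37 (adjusted p = 0.0751, 0.0605 and 0.0605), and Snrnp200, Birc5 and Aurkb did not pass either (adjusted p = 0.0761, 0.0647 and 0.0761). Of the genes named by the rule, by fry Trp53 and Bcor passed and the others did not (adjusted p from 0.112 to 0.259), and by robust rank aggregation Aurkb, Bcor, Birc5 and Tada1 did not (adjusted p = 0.072, 0.209, 0.125 and 0.06). Of single sgRNAs edgeR called 14 higher and 0 lower, with 507 at an unadjusted p below 0.05. The 3 largest were sg_Trp53_i3 at 6.65 ± 0.33, sg_Trp53_i4 at 6.39 ± 0.43 and sg_Trp53_i5 at 6.34 ± 0.35 (adjusted p = 1.4e-05, 7.78e-05 and 2.11e-05). The 14 became 55 without Cre 05, 38 without Cre 50 and 9 without either sgRNA library, and total counts gave 10 higher and 8 lower. By the Wald test of DESeq2, 65 were lower.

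In the gene lists for Cre over sgRNA, the broadly essential genes fell, with a mean of −0.88 ± 0.07 over 41 genes (adjusted p = 9.85e-15; adjusted p = 0.134 with an estimated correlation). Birc5 and Aurkb fell, and adjusted over the list alone 16 fell; Kansl3, of the MSL-related NSL acetyltransferase complex, at −1.64 ± 0.82 (adjusted p = 0.0481 without Cre 05) and Ruvbl2 at −1.58 ± 0.29 did not pass over all genes. The mitotic list fell, with a mean of −0.96 ± 0.52 over 4 genes (adjusted p = 0.000982; adjusted p = 0.193 with an estimated correlation; adjusted p = 0.0925 against random lists; adjusted p = 0.137 without Cre 05; a mean of −1.76 without Cre 50), with Birc5 and Aurkb past the gene threshold and 3 adjusted over the list alone, Aurka at −1.41 ± 0.33 and Gsg2 at 0.61 ± 0.47. The cohesin and CTCF list, measured by 3 cohesin genes and not by Ctcf, fell with a mean of −0.96 ± 0.15 (adjusted p = 0.0333 by camera, 0.291 with an estimated correlation and 0.0925 against random lists). Of the 3 genes, 0 passed over all genes or adjusted over the list alone. Rad21 was at −1.24 ± 0.79, Smc1a at −0.90 ± 0.35 and Smc3 at −0.75 ± 0.42. The cohesin call was lost without Cre 05 (mean −1.51, adjusted p = 0.0608), Cre 50 (adjusted p = 0.223) or sgRNA 05 (adjusted p = 0.0592), and with total counts (adjusted p = 0.0876).

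The p53 list tested higher in Cre over sgRNA (adjusted p = 2.64e-06; adjusted p = 0.134 with an estimated correlation; adjusted p = 0.0925 against random lists), with a mean of 0.34 ± 0.65 and a median of −0.03 over 11 genes. Trp53 and Atm rose and 9 genes did not pass; adjusted over the list alone, 3 were higher and 2 lower. Brca2, at −1.82 ± 0.96, and Brca1, also of homologous recombination, at −1.10 ± 0.51 did not pass over all genes. Without the Trp53 sgRNAs the list mean was −0.19 (adjusted p = 0.83). It was 0.17 without Cre 05 (adjusted p = 0.000706). Total counts, which lower all sgRNAs alike, put it at −0.13, while its test, relative to all sgRNAs, still pointed higher (adjusted p = 2.67e-07).

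The other 16 lists did not pass for Cre over sgRNA, with adjusted p from 0.152 to 0.828. Means were −0.50 ± 0.20 for histone chaperones, −0.34 ± 0.16 for BET and elongation, −0.30 ± 0.15 for TIP60/NuA4, −0.25 ± 0.15 for COMPASS/MLL, −0.19 ± 0.15 for arginine methyltransferases, −0.16 ± 0.08 for NuRD, −0.14 ± 0.12 for DNA methylation and −0.06 ± 0.09 for SWI/SNF. Histone demethylases were at 0.08 ± 0.09, PRC1 at 0.04 ± 0.11 and SAGA/ATAC at 0.02 ± 0.13. Mean and median differed in sign for MOZ/HBO1/MSL, at −0.14 and 0.05, INO80/SRCAP, at −0.12 and 0.12, PRC2, at −0.01 and 0.12, histone deacetylases and sirtuins, at −0.10 and 0.02, and H3K9 methylation and HP1, at −0.08 and 0.14. In the last 3 of these the test pointed higher.

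**Figure D3:**
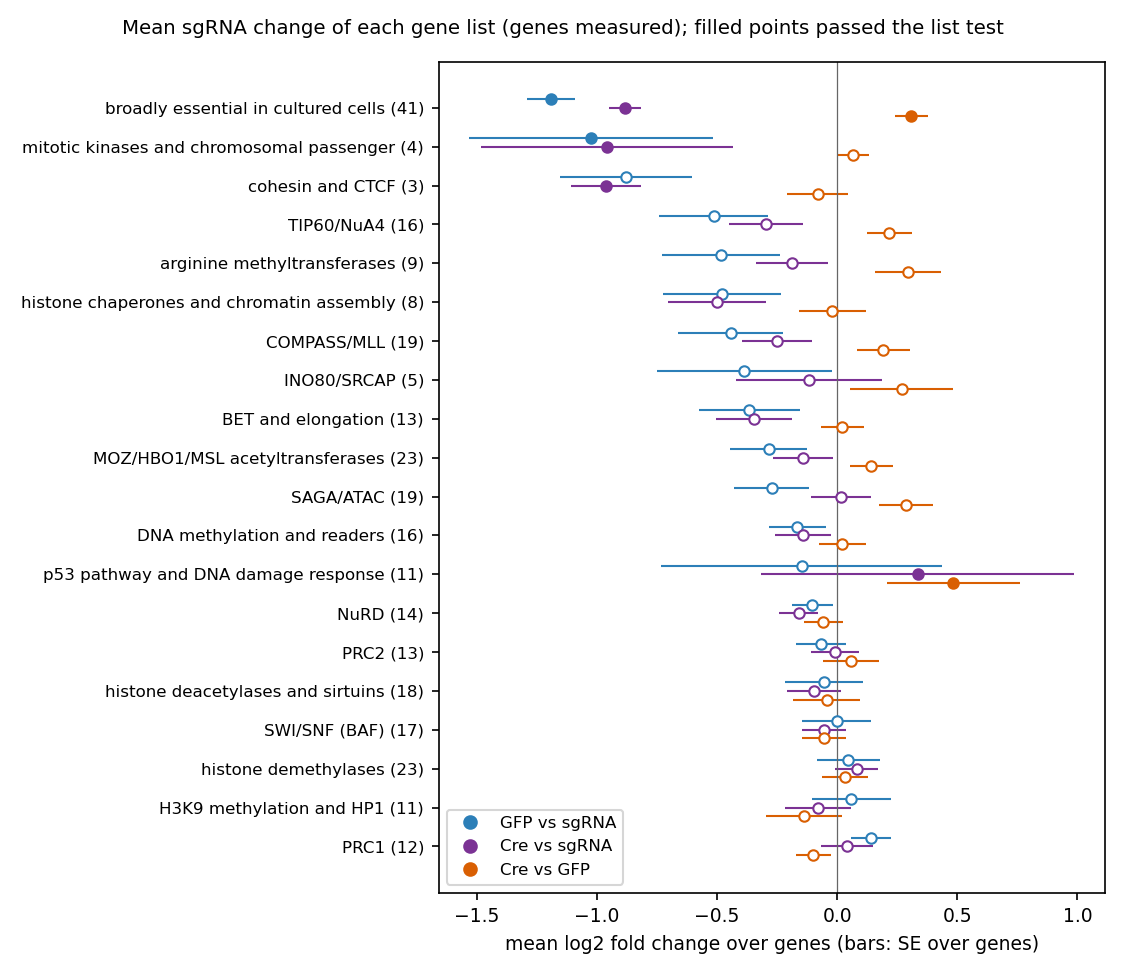
Mean log2 fold change over the genes of each list (horizontal axis, bars 1 SE over genes) for the 20 lists and 3 comparisons, with the number of genes measured in brackets and filled points for lists past the camera threshold. The broadly essential list lies at −1.19 for GFP over sgRNA, −0.88 for Cre over sgRNA and 0.31 for Cre over GFP.

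Between the libraries numbered 05 and 50, edgeR with a term for the construct called 0 of 3595 sgRNAs, with 294 at an unadjusted p below 0.05; no other tool was run for this comparison. The count was 4 without either Cre library and 7 without either sgRNA library. Across 3595 sgRNAs, log2 Cre over GFP in 05 and in 50, which share no library, had a Pearson correlation of 0.138 and a Spearman correlation of 0.139. Across the means of 720 genes these were 0.314 and 0.267, and without Trp53 the Pearson value was 0.299. sgRNAs and genes are not independent replicates, so no p is attached to these values. Log2 CPM had a Pearson correlation of 0.887 between Cre 50 and GFP 50 and 0.826 between Cre 05 and GFP 05. It was 0.818 for both Cre and GFP pairs of unlike number, 0.827 within Cre and 0.848 within GFP. Cre 50 and GFP 50 were nearer sgRNA 05 (0.852 and 0.840) than sgRNA 50 (0.808 and 0.795). Whether libraries of one number are paired is therefore open.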

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

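Factors from the msCon sgRNAs, the fit without the Trp53 sgRNAs and the lists with a library left out were chosen after the data had been seen. The planned factors from negative control sgRNAs were not run, because the names fixed for them matched 0 labels. Across the alternatives tried, named genes kept their direction and their side of the threshold 800 times, lost the threshold 151 times and gained it 18 times. The 800 include genes named as not past the threshold that stayed so, while only genes past it could make up the 151. The share of calls that were lost is therefore larger than these totals show. Lists kept both 63 times, lost the threshold 23 times and reversed 2 times, and named sgRNAs kept both 148 times and lost the threshold 23 times. With libraries thinned to the smallest total, the 12 values of the Gini index and of sgRNAs at 0 moved by less than the spread between libraries. The library of smallest total could not move, and no call was rerun on thinned counts. How far depth limited the calls was therefore not tested. The correlation of Cre over GFP between 05 and 50 was 0.138, and 0.137 to 0.142 under the alternatives. Where a group was left with 1 library, that library is assumed to vary like the other groups. Where no reason is given beside a change, the cause was not tested.

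With the title number as a replicate block, sgRNA counts moved from 4 to 15 (13 higher, 2 lower) for Cre over GFP, from 58 to 321 for GFP over sgRNA and from 14 to 45 for Cre over sgRNA. Lists in GFP over sgRNA went from 2 to 4, and gene counts stayed within 1.5 times, with 9 higher and 0 lower by camera for Cre over GFP against 9 and 1 without it. Of those 9, 8 were among the 10; Tada2a and Trp53bp1 (both adjusted p = 0.0697) did not pass, nor did Birc5 in Cre over sgRNA (adjusted p = 0.0603), where 17 genes passed, 11 among the 12. Whether the numbers pair the libraries is open. Deviations from the group means correlated at 0.223 for Cre and GFP, 0.00757 for Cre and sgRNA and 0.0959 for GFP and sgRNA.

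Leaving out 1 library at a time gave 0 to 23 sgRNAs, 1 to 10 genes and 0 to 2 lists for Cre over GFP (4, 10 and 2 with all 6). For GFP over sgRNA it gave 6 to 229 sgRNAs, 24 to 49 genes and 1 to 3 lists (58, 45 and 2 with all 6), and for Cre over sgRNA 9 to 55, 3 to 24 and 2 to 4 (14, 12 and 4 with all 6). For 05 against 50 it gave 0 to 7 sgRNAs. The essential list in Cre over GFP ran from −0.00141, without Cre 05 and reversed in sign, to 0.57 without GFP 50. The 0 sgRNAs by edgeR came without GFP 05 (323 at an unadjusted p below 0.05) and without GFP 50 (630). The 0 lists by camera came without Cre 05 (3 at an unadjusted p below 0.05) and without GFP 50 (4).

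Gene splits for Cre over GFP were also 9 and 0 with DESeq2 size factors or msCon factors. In GFP over sgRNA, total counts gave 185 sgRNAs, msCon factors 188, a mean of at least 100 counts 93 and only the 2 groups compared 262. In Cre over GFP, msCon factors gave 0 sgRNAs by edgeR (361 at an unadjusted p below 0.05). In Cre over sgRNA, total counts gave 5 genes and only the 2 groups compared 26.

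Without the Trp53 sgRNAs, Cre over GFP had 1 sgRNA and 0 lists by camera (3 at an unadjusted p below 0.05), GFP over sgRNA 38 sgRNAs, and Cre over sgRNA 8 sgRNAs and 28 genes. The p53 list in Cre over sgRNA reversed to −0.19 (adjusted p = 0.83 by camera), as it then lacks its largest member.

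The Wald test of DESeq2 called 66 sgRNAs for Cre over GFP (54 higher, 12 lower), 442 for GFP over sgRNA (130 and 312) and 144 for Cre over sgRNA (79 and 65). Camera with an estimated correlation called 0 genes and 0 of the 20 lists fixed beforehand in all 3 comparisons. At an unadjusted p below 0.05 it had 4, 18 and 10 genes and 2, 1 and 3 lists, in the order Cre over GFP, GFP over sgRNA and Cre over sgRNA. On simulated data it made no call even for genes changed by a log2 of 2, so its 0 genes say little. Lists were also run on the simulated data, but their result is not given here, so its 0 lists are not weighed against it. Counts summed per gene called 3, 160 and 85 genes in that order. Fry called 0 genes for Cre over GFP (105 at an unadjusted p below 0.05), where robust rank aggregation called 4, 34 for GFP over sgRNA (13 among the 45 of the preset correlation) and 5 for Cre over sgRNA (2 among the 12), while robust rank aggregation called 19 (17 among the 45) and 11 (7 among the 12). Random lists, which take genes as the unit, left 1 list in each comparison, the broadly essential list.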

Other observations

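The tests of the lists below, of reads taken by Trp53, of Trp53 itself, of single sgRNAs and of the title numbers were chosen after results had been seen, while 3 tests on genes lost with GFP were fixed before their own results were seen.

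The library also holds groups that no list fixed beforehand covers. For these, 5 lists were written after the genes past the threshold were known, so their p-values (camera, adjusted over the 5) describe the groups and are not independent evidence. Genes of the spliceosome and of snRNP assembly fell in GFP over sgRNA, with a mean log2 fold change of −1.26 ± 0.09 (SE over 47 genes; adjusted p = 3.83e-20; adjusted p = 0.0385 with an estimated correlation) and 45 of 47 below 0. Of these, 9 fell: Gemin2, Pdcd7, Snrnp40, Snrnp48, Snrpa, Snrpb, Snrpc, Snrpf and U2af1. In Cre over sgRNA the list fell with a mean of −0.93 ± 0.07 (adjusted p = 7.15e-16; adjusted p = 0.0699 with an estimated correlation), 47 of 47 were below 0, and Snrnp200 and Snrnp40 fell. In Cre over GFP it rose with a mean of 0.33 ± 0.09 (adjusted p = 0.00487; adjusted p = 0.325 with an estimated correlation), 0.45 in 05 and 0.26 in 50, with Gemin2, Snrnp48 and Snrpa higher. That mean was 0.07 without Cre 05 (adjusted p = 0.176), 0.12 without Cre 50 (adjusted p = 0.0182) and 0.74 without GFP 50 (adjusted p = 0.016).

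Ribosome biogenesis genes fell in GFP over sgRNA, with a mean of −1.39 ± 0.30 over 10 genes (adjusted p = 1.43e-08; adjusted p = 0.0821 with an estimated correlation), with Emg1, Las1l, Nat10 and Pelp1 past the gene threshold. In Cre over sgRNA the list fell with a mean of −0.87 ± 0.20 (adjusted p = 7.99e-07; adjusted p = 0.0956 with an estimated correlation), with 0 genes past it over all genes and 6 adjusted over the list alone. TFIID and TBP fell in GFP over sgRNA, with a mean of −0.98 ± 0.24 over 10 genes (adjusted p = 6.89e-05; adjusted p = 0.0385 with an estimated correlation), Taf6 among the genes past the threshold, and in Cre over sgRNA with a mean of −0.58 ± 0.18 (adjusted p = 0.0017; adjusted p = 0.0699 with an estimated correlation). In Cre over GFP these 2 lists were at 0.52 ± 0.26 (adjusted p = 0.0757) and 0.40 ± 0.16 (adjusted p = 0.112), and neither passed by camera with all 6 libraries. Against random lists ribosome biogenesis passed (adjusted p = 0.0112), and TFIID and TBP did not (adjusted p = 0.0515). Ribosome biogenesis ran from 0.35 without Cre 05 (adjusted p = 0.45) to 0.85 without GFP 50 (adjusted p = 0.016), where it passed, and TFIID and TBP from 0.06 without Cre 50 (adjusted p = 0.383) to 0.58 without GFP 50 (adjusted p = 0.366). N-terminal acetyltransferases did not pass in any comparison, with means of 0.10 ± 0.12, −0.09 ± 0.16 and 0.01 ± 0.12 for Cre over GFP, GFP over sgRNA and Cre over sgRNA. The 14 testis and germline factors were at 0.19 ± 0.09 in GFP over sgRNA (adjusted p = 0.0388) and 0.27 ± 0.08 in Cre over sgRNA (adjusted p = 0.0495). Both calls were lost with an estimated correlation (adjusted p = 0.0859 and 0.0956), the first without Cre 05, Cre 50 or GFP 50 (adjusted p = 0.0547, 0.0517 and 0.0654) and the second without Cre 05 or Cre 50 (adjusted p = 0.0944 and 0.161).

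sgRNAs of genes that were low in GFP over sgRNA were less low in Cre over sgRNA, with exceptions such as Birc5 (−1.40 and −1.52) and Snrnp200 (−0.71 and −1.79). Chance values held by 1 GFP library are argued against, since the tenth of genes lowest in one number exceeded the others in log2 Cre over GFP of the other number by 0.65 ± 0.09 and 0.36 ± 0.06. Reads taken by the Trp53 sgRNAs scale all other sgRNAs of a library alike, so the same 2 differences argue against them as the whole cause, while the essential list decides less, as it exceeded other genes by 0.25 ± 0.07 without these sgRNAs but by 0.04 ± 0.10 when Cre 05 was left out too. Chance values common to both GFP libraries cannot be told apart from a shift of these genes, since the msCon slopes of −0.29 ± 0.24 and −0.21 ± 0.17 lay within their error of those of gene sgRNAs at −0.27 ± 0.02 and −0.11 ± 0.01, the smaller difference being −0.0148. The lowest and highest sets of genes were taken without Trp53. Among the other genes, taken as sets, weaker selection in the Cre libraries met its test. The 72 genes highest in GFP over sgRNA of 50 differed from the others in Cre over GFP of 05 by −0.49 ± 0.07. The 72 highest in 05 differed by −0.16 ± 0.05 in 50. Chance values common to both GFP libraries would give such values too. Trp53 moved the other way, with means of 4.17 in GFP over sgRNA and 2.19 in Cre over GFP. These means argue against weaker selection on every sgRNA, Trp53 included. Single genes among the others also left the pattern. Atm was at 0.35 in GFP over sgRNA, not past the threshold, and at 0.90 in Cre over GFP. Tada3 was at −1.0 in GFP over sgRNA and at 0.58 in Cre over sgRNA, neither past the threshold. Fewer divisions after Cre, slower growth without Upf2 and a relief specific to loss of Upf2 may each underlie the pattern and were not tested.

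Trp53 sgRNAs were higher in Cre than in GFP. Expansion of single clones that carry a few of the sgRNAs is argued against, since all 5 sgRNAs were above a log2 of 1 in both numbers, the lowest at 1.02. Weaker selection on every sgRNA in Cre is argued against as well, since it brings values nearer 0 and would raise only sgRNAs that are low in GFP over sgRNA, while the 5 had a mean of 4.20 there. A candidate explanation is that cells without Upf2, or cells that received Cre, gain more from loss of p53 than cells with GFP. The design does not separate loss of Upf2 from Cre itself, since cells with Cre and no floxed Upf2 are not among these libraries.

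Of 3562 sgRNAs of genes other than Trp53, 2 stood at 4-fold or more above their sgRNA library in all 4 Cre and GFP libraries. sg_Foxa1_i1 had a mean of 3.04, against 0.08 for the other 4 sgRNAs of Foxa1, and sg_Usp27x_i2 had a mean of 3.09, against −0.34 for the others of Usp27x. Drift that is independent in each library is argued against, since 10000 draws with the libraries shuffled gave a mean of 0, and draws that kept Cre and GFP of one number together gave a mean of 0.0229. An effect of these sgRNAs on another gene, or an expansion of their cells before the cultures were parted, may account for them and was not tested.

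The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05; the split by title number called 0 sgRNAs and the highest other split called 0.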
